A study of Mus musculus with 24 samples.

How the data were processed

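RNA from 24 samples of primary mouse dermal fibroblasts (WT, NIK X mut and NIK knockout, untreated or after TWEAK for 6 or 24 h) had been made into 3′ UMI libraries by bulk MARS-seq from 50 ng of total RNA each. Per the labels, RNA was extracted with either of 2 kits, without saying which kit served which sample. The submitters' processing notes name cutadapt, STAR 2.7.10a, HTSeq and DESeq2 and the genome build GRCm38. The deposited table gives UMI counts per gene and library, and the authors' log2 fold changes and adjusted p-value for 15 comparisons of groups, with a column of calls. Its counts are whole numbers that were not normalised, and every gene in it reaches a count of at least 6 in some library, so genes below that had been removed by the authors.

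Library totals ranged from 889863 to 4342981 UMIs. A count of 0 allows up to 3 counts of a library's total. UMIs remove PCR copies, but counting intervals cover counting error only. For genes named with 3 or fewer UMIs in a group, the ratio of raw UMIs is given with an exact Poisson interval, or with 0 UMIs a bound against a floor of 3 UMIs over the group.

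Counts were analysed in R 4.3.3 with edgeR 4.0.16. The 13479 genes were filtered with filterByExpr by group, which kept 11337 and left out 2142, and normalised by TMM. The 24 libraries in 9 groups of genotype and time were fitted together with glmQLFit, and 15 contrasts were tested with the quasi-likelihood F test at a Benjamini-Hochberg adjusted p under 0.05. These were the responses at 6 and 24 h in each genotype, the differences between genotypes in response, and the differences before treatment. The SE of a log2 change was its size divided by the square root of F. CPM values are TMM-normalised, and log2 CPM used a prior count of 2. The replicate origin and the authors' model are not stated, so the replicate number was left out of the fit and used as a block in an alternative.

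Whether equal numbers pair libraries was checked from deviations from the group means of genes with a mean log2 CPM above 4. Same-numbered WT libraries correlated at 0.328 to 0.688 across genes and each matched its own number best, but these values include the difference between library sets. Within a set they were 0.438 and 0.534 for WT replicates 1 and 2 at 6 and 24 h, and 0.116 and 0.107 for replicates 3 and 4. For MUT the values were 0.0633 and 0.0710, and for KO -0.282 and -0.134. Pairing was thus clear in WT replicates 1 and 2, weak in WT replicates 3 and 4 and in MUT, and not seen in KO, and a block with the KO numbers crossed was added after seeing the data. limma-voom gave a consensus correlation within cultures of 0.231.

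The design, the alternatives, the rule for named genes and 27 gene lists were fixed before the data were examined. In each contrast the genes eligible to be named were Map3k14, Chuk, Ikbkb, Nfkb2, Relb and Tnfrsf12a always, then the 8 largest rises and 8 largest falls among genes past the test with at least 5 CPM in the higher group and no overlap of libraries in comparisons of 2 groups, and then up to 4 members of each list with the smallest adjusted p among those past the test. Unnamed gene models were left out of the largest changes. The lists covered NF-kB components and targets, chemokines, cytokines, adhesion molecules, interferon and MHC class I genes, complement, matrix, contractile, cell cycle, p53, immediate-early, metabolic and stress genes, fibroblast markers, mitochondrially encoded genes and markers of other cell types. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 27 lists of a contrast. An estimated correlation, fry and camera with the culture as a block were alternatives, the last added after seeing the data. Members past the test are counted over all genes and adjusted over the list alone.

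The response retained was computed per culture, each treated library against the untreated library of the same number, from genes past the test in WT with an absolute log2 change of at least 1. Each WT culture was measured on genes called in the other WT cultures. The design measured MUT and KO on genes called in all 4 and compared the genotypes by permutation, but the lists of the WT cultures were shorter and favoured larger changes. That test is not reported for WT, and MUT and KO were measured on the list of each WT culture instead, a change made after seeing the data. For percentages, genes were chosen in 2 WT cultures (6 choices, of which those with fewer than 10 genes were left out) and measured in the other WT cultures and in MUT and KO. Equal numbers were not seen to pair in KO. The mean of the untreated libraries of a genotype as baseline gave 98.7% and 75.8% in MUT and 42.4% and 19.0% in KO at 6 and 24 h. MUT and KO cultures were compared with two-sided exact permutation tests. Comparisons that share control libraries were set beside 100 simulations of unchanged groups and beside values with the WT libraries divided between them.

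Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter, an absolute log2 change of at least 1, each library or number left out, WT reduced to 2 numbers, only the groups of a contrast, limma-voom with the culture as a random block, and the culture as a fixed block. After seeing the data, library sets as separate groups were added. The recovery of changes of log2 1 and 2 was tested on simulated data with 100 changed genes per size. Gene positions came from a GRCm38 annotation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No sample or count column was left out of the analysis.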

Results

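Gene expression was measured by a bulk version of MARS-seq, which counts transcripts from their 3′ ends with unique molecular identifiers (UMIs), in primary mouse dermal fibroblasts at passage 5. The cells came from wild-type mice (WT), from mice labelled NIK X mut (MUT; the labels do not say what the mutation changes) and from NIK knockout mice (KO). They were left untreated or exposed to TWEAK at 100 ng/ml, a TNF-family cytokine that signals through the receptor Fn14, for 6 or 24 h. The library names of the early time point give 3 h where the sample descriptions give 6 h, and it is called 6 h throughout. Each time point had 4 WT, 2 MUT and 2 KO libraries, 24 in all. The labels give no untreated library at 6 or 24 h, so changes after TWEAK may include changes with time in culture. The labels do not state whether replicates came from separate mice, so the p-values measure the spread between samples. WT replicate 1 held 42 Xist and 0 Y-linked UMIs, while WT replicates 2, 3 and 4 held 228, 138 and 127 Y-linked UMIs. Replicate 1 thus came from a different animal than those, and the origin of the others stays open. The libraries of a genotype that carry the same replicate number are called a culture here.

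The libraries held between 889863 UMIs (WT 6 h, replicate 1) and 4342981 UMIs (MUT untreated, replicate 1), with 12333 to 13338 genes detected. Median totals per group were lowest for KO at 6 h (1480653) and highest for untreated MUT (3691611). Of 13479 genes in the count table, 11337 were tested. Depth was enough to recover most simulated changes of log2 2 between time points. In simulations with 100 changed genes per size, 92% were recovered in WT at 6 h, 78% in MUT and 70% in KO. Changes of log2 1 were recovered less often, in 60%, 29% and 29% respectively.

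NIK is the kinase that starts the noncanonical NF-kB pathway, and its gene, Map3k14, served as a check of the genotypes. Map3k14 (GRCm38 chromosome 11, 103219762 to 103267472, minus strand) was nearly absent from the knockout, with 4 UMIs over the 6 KO libraries against 34 to 186 per WT library and 63 to 164 per MUT library. The KO count corresponds to 0.390 CPM of the raw totals (95% exact binomial interval 0.106 to 0.998, which covers counting error only), or 1.08% of the WT level. MUT cells kept the transcript, at 26.8 ± 1.79 CPM untreated (SD, n = 2) beside 21.3 ± 4.41 CPM in WT (SD, n = 4). The other genes followed in every comparison were Chuk, encoding IKK1 (chromosome 19, 44073335 to 44107480), Ikbkb, encoding IKK2 (chromosome 8, 22659212 to 22706589), Nfkb2 (chromosome 19, 46304320 to 46312385), Relb (chromosome 7, 19606217 to 19629438) and Tnfrsf12a, encoding Fn14 (chromosome 17, 23675445 to 23677468). All are annotated as protein-coding.

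The first comparison asked whether the genotypes differed before TWEAK. Untreated KO cells differed from WT in 1 gene, Map3k14 itself, which was lower by a log2 change of -6.06 ± 0.68 (SE; adjusted p = 0.000137, n = 2 and 4). The untreated KO libraries held 1 UMI of it against 207 in WT, so the fitted size depends on the prior count and was -8.67 to -5.44 over the alternatives, 3 of 19 of which did not call it. The ratio of raw UMIs was 78.7 (95% exact interval 13.97 to 3123, counting error only). The same gene was the 1 difference between MUT and KO, at 6.39 ± 0.69 (adjusted p = 6.86e-05, n = 2 and 2; 5.80 to 8.999 over the alternatives, 2 of 15 of which did not call it). No gene passed between MUT and WT by edgeR, where 815 had an unadjusted p under 0.05 (566.85 by chance) and DESeq2 called 2. Nfkb2 (-0.45 ± 0.17) and Relb (-0.49 ± 0.19) were among those not past the test in MUT (adjusted p = 0.679 for both). Between KO and WT, Nfkb2 differed by -0.04 ± 0.17 and Relb by -0.16 ± 0.20. DESeq2 called 0 genes between KO and WT and 12 between MUT and KO (560 in edgeR on those libraries alone), where 537 and 1482 had an unadjusted p under 0.05 in edgeR.

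Untreated WT libraries did not form a single cluster. On principal component 1, with 30.9% of the variance, all libraries of WT replicates 1 and 2 and of KO lay between -29.4 and -6.11, and those of WT replicates 3 and 4 and of MUT lay between 4.47 and 28.7. These are called library sets here, and they follow no label. Cell cycle genes moved with the sets: their median was 1.65 higher (log2) in untreated MUT than in untreated KO, with 35 of 47 higher when adjusted over the list alone and 0 over all genes (adjusted p = 0.48 with an estimated correlation). Against the WT libraries of its own set, the same MUT and KO difference had a median of -0.20. Compared with WT replicates 1 and 2 alone, untreated MUT differed in 1075 genes and KO in 2, and compared with replicates 3 and 4 alone, MUT differed in 4 and KO in 783. In a fit with the sets as separate groups, chosen after seeing the data, each mutant was compared with the WT libraries of its set. Map3k14 (-6.01), Lgr5 (-2.36) and the unnamed model Gm6136 (4.37) then passed for KO and Pdlim1 (1.38) passed for MUT. Map3k14 (6.29), Lgr5 (3.91) and Gm6136 (-7.19) passed between MUT and KO, each mutant taken relative to its WT set.

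**Figure D1:**
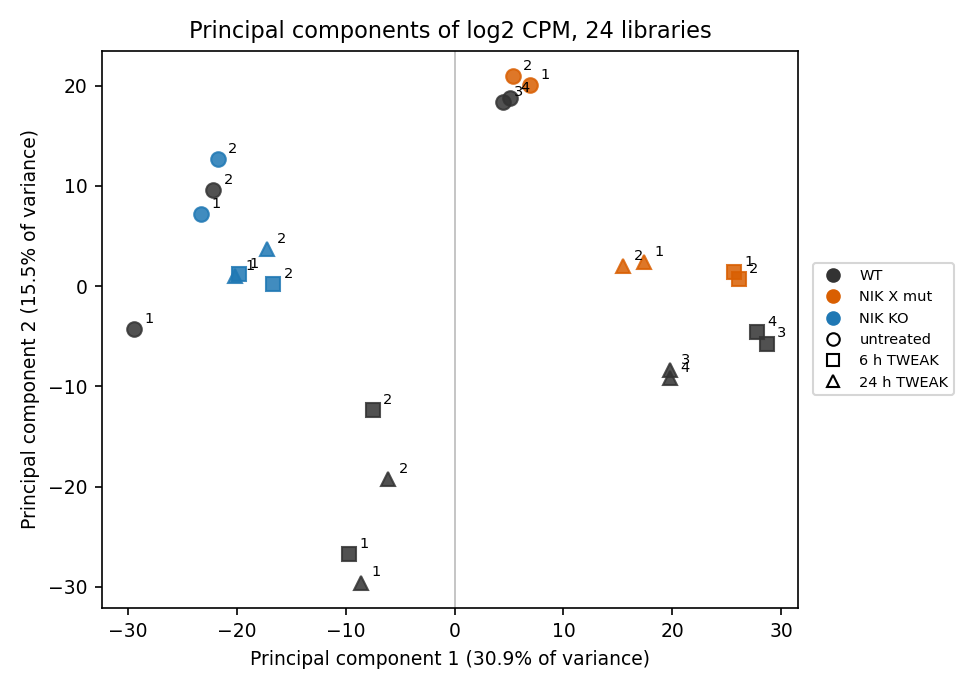
Principal component 1 against principal component 2 (30.9% and 15.5% of the variance) of log2 CPM of 7289 genes in the 24 libraries; colours give the genotype, shapes the time, and numbers the replicate. All libraries of WT replicates 1 and 2 and KO lie at or below -6.11 on component 1, and all libraries of WT replicates 3 and 4 and MUT at or above 4.47.

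The differences of MUT and of KO from WT before treatment share their WT libraries, which alone makes them alike. Across 11337 genes their correlation was -0.0798, against 0.337 in simulated unchanged groups, which were drawn without library sets. It ranged from -0.586 to -0.0542 when the WT libraries were divided between both comparisons. The value of -0.586 set each mutant against the WT libraries of the other set, and -0.0542 against those of its own set. The library sets enter these correlations, which therefore do not show that MUT and KO differ from WT in opposite directions. Genes are not independent replicates, so no p-value is given for a correlation across genes.

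TWEAK for 6 h raised the transcripts of both NF-kB branches in WT cells (n = 4 per time). Nfkb2, which encodes the precursor that NIK signalling processes, rose from 101.9 ± 14.1 to 542 ± 58.3 CPM (SD; log2 change 2.41 ± 0.14, SE), and Relb, its partner subunit, rose by 2.54 ± 0.15. Map3k14 itself rose by 1.18 ± 0.24 (adjusted p = 0.00369), and Traf3, an adaptor that keeps NIK protein low, rose by 1.19 ± 0.17. Nfkbie and Nfkbia, which encode inhibitors of the canonical branch, rose by 4.16 ± 0.24 and 3.52 ± 0.24. Transcripts of Chuk (0.15 ± 0.21, adjusted p = 0.782), Ikbkb (0.50 ± 0.16, adjusted p = 0.0752) and Tnfrsf12a (0.91 ± 0.35, adjusted p = 0.136) did not pass the test.

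By gene list, 8 of 13 noncanonical NF-kB components rose (9 rose and 1 fell adjusted over the list alone), as did 11 of 18 canonical components and feedback genes (12 over the list alone) and 9 of 15 survival and stress targets (11 over the list alone), among them Bdkrb1 (5.28 ± 0.75), the bradykinin receptor, and Ptges (1.91 ± 0.28), a prostaglandin synthase. Chemokines showed the largest median of the 27 lists, 2.88, and 11 of 16 rose (13 rose and 1 fell over the list alone). Ccl2, which attracts monocytes, rose by 3.42 ± 0.20, Cxcl16 by 3.42 ± 0.20, Cxcl10 by 4.79 ± 0.37 and Ccl5 by 4.35 ± 0.42. Of 20 cytokines and growth factors 7 rose (12 over the list alone), including Csf1 (2.02 ± 0.19) and Csf2 (7.27 ± 0.85), colony-stimulating factors of macrophages and granulocytes. Csf2 had no UMI in untreated WT libraries, so its fitted fold depends on the prior count, and against a floor of 3 UMIs over that group it was at least 26.0-fold higher. Of 10 adhesion molecules 7 rose (9 over the list alone), with Icam1 at 3.52 ± 0.25 and Vcam1 at 1.89 ± 0.20. These 6 lists also passed camera with an estimated correlation, with adjusted p from 2.7e-06 for the noncanonical list to 0.026 for cytokines.

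Other lists passed in WT at 6 h only with the preset correlation. Immediate-early genes had 12 of 24 members up (14 over the list alone), such as Jun (1.63 ± 0.20) and Egr2 (3.15 ± 0.42), with an adjusted p = 0.119 with an estimated correlation. Interferon-stimulated genes had 5 of 46 up (6 over the list alone), including Gbp2 (1.81 ± 0.30) and Irf1 (1.12 ± 0.21), with an adjusted p = 0.509 with an estimated correlation. For antigen presentation by MHC class I, 4 of 20 rose (9 over the list alone), and the adjusted p was 0.14 with an estimated correlation. Cell cycle genes had a median of -0.74 with 1 of 47 past the test, E2f1 (-0.77 ± 0.16), and the list gave an adjusted p = 0.549 with an estimated correlation. That median differed between the library sets, at -0.09 and 0.01 in WT cultures 1 and 2 and -1.10 and -0.94 in cultures 3 and 4. Cholesterol and fatty acid synthesis had a median of -0.42 with 0 of 28 past the test (adjusted p = 0.622 with an estimated correlation).

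The remaining lists did not pass camera in WT at 6 h, but with the culture as a block, chosen after seeing the data, matrix proteases and inhibitors (adjusted p = 0.0135) and complement (adjusted p = 0.0236) did. Members past the test numbered 5 up and 1 down of 24 matrix proteases and inhibitors, 5 up of 29 contractile and TGF-beta-induced genes, 3 up of 18 oxidative stress genes, 1 up and 2 down of 20 p53 targets, 2 down of 20 unfolded protein response genes, 1 up and 2 down of 17 dermal fibroblast markers, 1 up of 27 glycolysis and hypoxia genes, and 1 up of 7 complement genes (C3, 2.38 ± 0.55). None of 33 collagens and matrix proteins and none of 8 mitochondrially encoded genes passed. Of the markers of other cell types, 1 of 4 keratinocyte genes rose (Ivl, 3.54 ± 1.04, adjusted p = 0.0437), but with the library sets as groups Ivl changed by 0.76 (adjusted p = 0.924) and it did not pass in 12 of 21 alternatives. For the other types, 0 of 5 adipocyte, 0 of 4 endothelial, 0 of 4 macrophage and leukocyte, 0 of 5 melanocyte and Schwann cell, and 0 of 8 skeletal muscle and pericyte genes passed.

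In all, 493 genes rose and 234 fell in WT at 6 h, 727 together, where 2109 had an unadjusted p under 0.05. Mmp9, a gelatinase, was among the largest rises (4.85 ± 0.67). The largest falls included the transcription factor genes Osr2 (-2.97 ± 0.50), Osr1 (-2.75 ± 0.24) and Dbp (-2.34 ± 0.38), and Twist1, a mesenchymal regulator, fell by 1.42 ± 0.16 on the log2 scale. With the culture as a block 1314 genes passed, and with the library sets as separate groups 1271 passed, of which 715 were among the 727. The count was 424 without the 6 h library of replicate 3, 457 without that of replicate 4 and 473 without the untreated library of replicate 2.

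After 24 h, the NF-kB transcripts in WT cells were still raised. Nfkb2 was 2.38 ± 0.14 (log2) above untreated cells and Relb was 3.99-fold higher (SE of the log2 change 0.15), with Map3k14 at 0.97 ± 0.23 (adjusted p = 0.0121; n = 4 per time). Traf1, a signalling adaptor, rose by 6.17 ± 0.43 and Ccl5, which attracts T cells, by 5.55 ± 0.42. Tapbp, Psmb10 and H2-K1, members of the list for antigen presentation by MHC class I, rose by 1.56 ± 0.17, 1.69 ± 0.20 and 1.68 ± 0.26. The largest falls included Cyp4b1 (-4.53 ± 0.60), Lgr5, a receptor for R-spondins (-4.52 ± 0.66), Lmcd1 (-3.92 ± 0.41) and Wnt4 (-3.50 ± 0.63).

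By list, 7 of 13 noncanonical components rose at 24 h (8 over the list alone), 10 of 18 canonical genes rose (12 over the list alone), 10 of 16 chemokines rose and 1, Cxcl14, fell (11 and 1 over the list alone), and 5 of 10 adhesion molecules rose (5 over the list alone). MHC class I presentation had 8 of 20 up (13 over the list alone). These 5 lists held with an estimated correlation, with adjusted p up to 0.0272 for MHC class I. Survival and stress targets had 3 of 15 up and 1 down (5 up and 1 down over the list alone; adjusted p = 0.152 with an estimated correlation), and interferon-stimulated genes had 9 of 46 up (14 over the list alone; adjusted p = 0.325 with an estimated correlation). Of 20 cytokines 4 rose and 2 fell, and the list did not pass camera.

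Among lists with negative medians at 24 h, 7 of 33 collagens and matrix proteins fell (8 adjusted over the list alone), including Lox, which crosslinks collagen (-0.65 ± 0.12), Col8a1 (-0.92 ± 0.20) and Col11a1 (-1.64 ± 0.41). That list passed camera with the preset correlation, and its adjusted p = 0.445 with an estimated correlation. Of 29 contractile and TGF-beta-induced genes 3 fell and 1 rose (8 and 1 over the list alone; adjusted p = 0.534 with an estimated correlation), and Itga11, a collagen-binding integrin, fell by 1.41 ± 0.13 on the log2 scale. For the unfolded protein response, 3 of 20 genes fell (6 over the list alone; adjusted p = 0.152 with an estimated correlation), namely Trib3 (-1.40 ± 0.17), Ddit3 (-0.93 ± 0.14) and Chac1 (-0.80 ± 0.16). Cell cycle genes had a median of 0.71, with 1 of 47 past the test (Ccnd1, 0.72 ± 0.15; adjusted p = 0.534 with an estimated correlation). In the fit with a block for the culture, 34 of these 47 genes rose at 24 h and 22 fell at 6 h. The 6 h fit averages over unlike cultures, with medians of -0.09 and 0.01 in WT cultures 1 and 2 and -1.10 and -0.94 in cultures 3 and 4. Of 33 collagens and matrix proteins, 18 fell and 1 rose at 24 h in that fit. The cholesterol list had a median of -0.41 (adjusted p = 0.72 with an estimated correlation). The skeletal muscle and pericyte list fell with the preset correlation (adjusted p = 0.534 with an estimated correlation), with 1 of 8 past the test, Mcam (-1.18 ± 0.28).

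The other lists did not pass camera in WT at 24 h. Of 17 fibroblast markers 2 rose and 4 fell, among them Cd34 (3.20 ± 0.37), Lrig1 (0.78 ± 0.16), Thy1 (-0.67 ± 0.16) and Twist1 (-0.98 ± 0.16). Members past the test numbered 3 up and 5 down of 24 matrix proteases and inhibitors, 5 up and 1 down of 24 immediate-early genes, 1 up and 1 down of 20 p53 targets, 1 down of 27 glycolysis and hypoxia genes (Adm, -1.41 ± 0.24) and 1 up of 7 complement genes (C3, 3.24 ± 0.51). None of 18 oxidative stress genes and none of 8 mitochondrially encoded genes passed. Of the markers of other cell types, 1 of 4 endothelial genes rose (Cdh5, 1.56 ± 0.41, adjusted p = 0.0225), 1 of 4 macrophage and leukocyte genes fell (Lyz2, -1.44 ± 0.39, adjusted p = 0.0280), and 0 of 4 keratinocyte, 0 of 5 adipocyte, and 0 of 5 melanocyte and Schwann cell genes passed.

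At 24 h 417 genes rose and 362 fell in WT, 779 together, where 2250 had an unadjusted p under 0.05. Of the genes that rose at 6 h, 231 also rose at 24 h, against 18.1 for independent lists, and of those that fell 95 also fell, against 7.47. Both responses share the untreated libraries, which alone makes them alike. Across 11337 genes their correlation was 0.599, against a mean of 0.475 (at most 0.504) in 100 simulations of unchanged groups, drawn without library sets. It was 0.168 to 0.448 (median 0.393) when the untreated libraries were divided between them. The values of 0.168 and 0.244 divided them along the library sets, so the set difference enters both. No gene called at both times moved in opposite directions in this fit, but 36 of 680 did with the culture as a block and 51 of 672 with the library sets as groups, of which 17 and 19 were cell cycle genes. With the culture as a block 1770 genes passed, and with the library sets as separate groups 1760 passed, 778 of the 779 among them. The count was 489 without all libraries of WT replicate 3, 497 without replicate 2 and 519 without replicate 4.

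**Figure D2:**
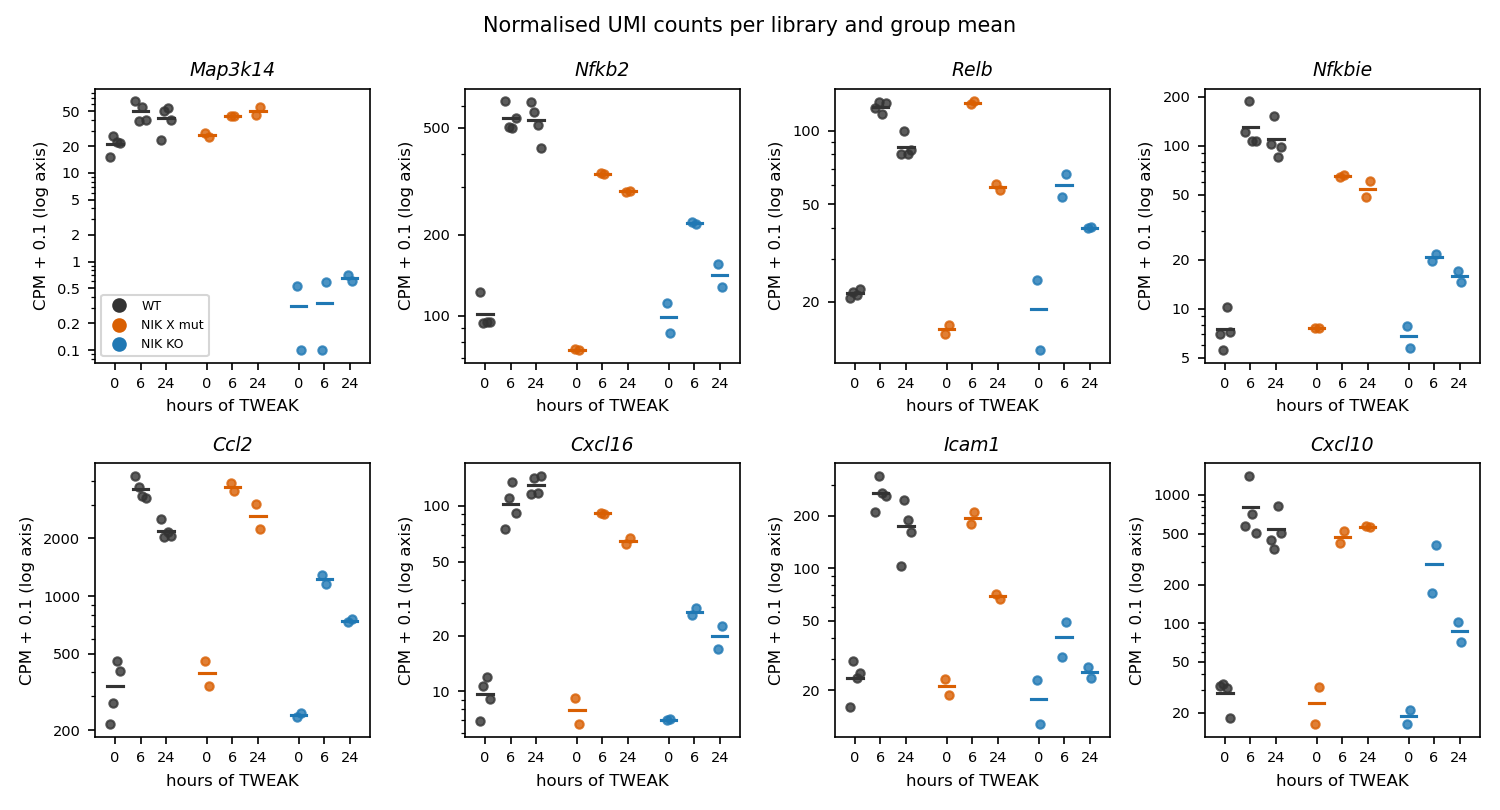
CPM plus 0.1 on a log axis for 8 genes at 0, 6 and 24 h of TWEAK; points are libraries (4 WT, 2 NIK X mut and 2 NIK KO per time) and bars are group means. Map3k14 stays below 1 CPM in every KO library, and Nfkb2 averages 531 CPM in WT, 290 in MUT and 142 in KO at 24 h.

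MUT cells also responded to TWEAK through the NF-kB transcripts (n = 2 per time). At 6 h Relb rose by 3.08 ± 0.21, Nfkb2 by 2.17 ± 0.20 and Nfkbie by 3.12 ± 0.32, and Ccl2, Cxcl16 and Icam1 rose by 3.21 ± 0.28, 3.51 ± 0.27 and 3.20 ± 0.35. Map3k14 (0.72 ± 0.32, adjusted p = 0.315) did not pass the test. Of the lists, 5 of 13 noncanonical (6 over the list alone), 9 of 18 canonical (12), 5 of 15 survival and stress (12), 10 of 16 chemokine (11), 4 of 20 cytokine (11) and 4 of 10 adhesion genes (6) rose, with the counts adjusted over the list alone in brackets. Immediate-early genes had 8 of 24 members up (16 up and 1 down over the list alone), including Egr2 (3.13 ± 0.55) and Fosl1 (2.02 ± 0.41). These 7 lists held with an estimated correlation. The falls included Osr2 (-3.23 ± 0.77), Dbp (-2.80 ± 0.55) and Twist1 (-1.16 ± 0.23). Cell cycle genes had a median of -0.96 with 1 of 47 past the test, Tk1 (-1.99 ± 0.50), and the list gave an adjusted p = 0.569 with an estimated correlation.

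At 24 h in MUT, Nfkb2 (1.95 ± 0.20), Relb (1.94 ± 0.21), Cxcl10 (4.58 ± 0.52), Ccl5 (4.37 ± 0.61) and Tapbp (1.81 ± 0.24) had risen, while Icam1 had risen by 1.71 ± 0.34. The noncanonical (4 of 13; 7 over the list alone), canonical (6 of 18; 10), chemokine (5 of 16; 10 up and 1 down) and MHC class I lists (3 of 20; 10) passed camera, and all 4 held with an estimated correlation. Interferon-stimulated genes had 2 of 46 members up over all genes and 26 adjusted over the list alone, with a median of 1.10 (adjusted p = 0.0723 with an estimated correlation). Falls included Acot11 (-2.21 ± 0.35), a thioesterase, and Mgll (-1.84 ± 0.37), a lipase.

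In MUT, 170 genes rose and 55 fell at 6 h, and 56 rose and 22 fell at 24 h. Of the rises in MUT, 149 had also risen in WT at 6 h (7.39 for independent lists) and 51 at 24 h (2.06 for independent lists). With only 2 libraries per time these counts depended on each of them, at 30 to 63 genes at 6 h and 17 to 23 at 24 h when any 1 library was left out. A fit of the MUT libraries alone, whose spread was not pooled with WT, called 1345 and 1104 genes, and the culture block gave 853 and 355, although the MUT numbers showed little sign of pairing.

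In KO cells a small part of the response passed the test at 6 h, and no gene did at 24 h (n = 2 per time). The 9 genes that rose at 6 h were Ccl2 (2.34 ± 0.28, adjusted p = 0.000266), Cxcl10 (3.98 ± 0.53), Relb (1.65 ± 0.22), Cxcl16 (1.95 ± 0.33), Nfkb2 (1.15 ± 0.20, adjusted p = 0.0205), Iigp1, an interferon-inducible GTPase (4.99 ± 0.89), Ccl20 (15.99-fold, SE of the log2 change 0.75), Nfkbia (1.79 ± 0.34) and Tnip1 (1.04 ± 0.20, adjusted p = 0.0474). None fell. Iigp1 had 2 UMIs in the untreated KO libraries and 55 at 6 h, a ratio of 34.2 (95% exact interval 9.02 to 289, counting error only). Its fitted change was 3.41 to 8.79 over the alternatives, and 7 of 15 did not call it. Of the 9 genes, 8 had also risen in WT, and the other, Iigp1, changed by 0.95 ± 0.44 in WT (adjusted p = 0.244). By list, 4 of 16 chemokines (7 over the list alone), 2 of 13 noncanonical genes (5) and 2 of 18 canonical genes (6) rose. Interferon-stimulated genes had a median of 0.94 with 1 of 46 up over all genes and 14 over the list alone, and MHC class I presentation had a median of 0.66 with 0 of 20 and 4. These 5 lists and the survival and stress targets held with an estimated correlation.

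At 24 h in KO, 382 genes had an unadjusted p under 0.05 in edgeR (566.85 by chance) and DESeq2 called 3. The library-set fit, chosen after seeing the data, also called 3, namely Ccl2 (1.63, adjusted p = 0.000204), Cxcl5 (1.72, adjusted p = 0.00162) and Cxcl1 (2.51, adjusted p = 0.00642), of which Ccl2 had an adjusted p = 0.0545 in the fit by group. Nfkb2 changed by 0.51 ± 0.20 (adjusted p = 1) and Relb by 1.06 ± 0.22 (adjusted p = 0.296). As lists, chemokines (median 1.29; 7 of 16 up over the list alone), interferon-stimulated genes (0.80; 9 of 46), MHC class I presentation (0.61; 6 of 20), canonical (3 of 18) and noncanonical genes (1 of 13) were raised, with adjusted p up to 0.0393 with an estimated correlation, while fry called 0 lists. The count of 9 at 6 h was 1 to 3 when any 1 of its 4 libraries was left out, and without both libraries of KO replicate 2 none of the 9 passed and 3 other genes were called, all falling. The count of 0 at 24 h was 1 without the untreated library of replicate 1. At this depth and n, 75% of simulated changes of log2 2 in KO at 24 h were recovered and 16% of changes of log2 1.

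**Figure D3:**
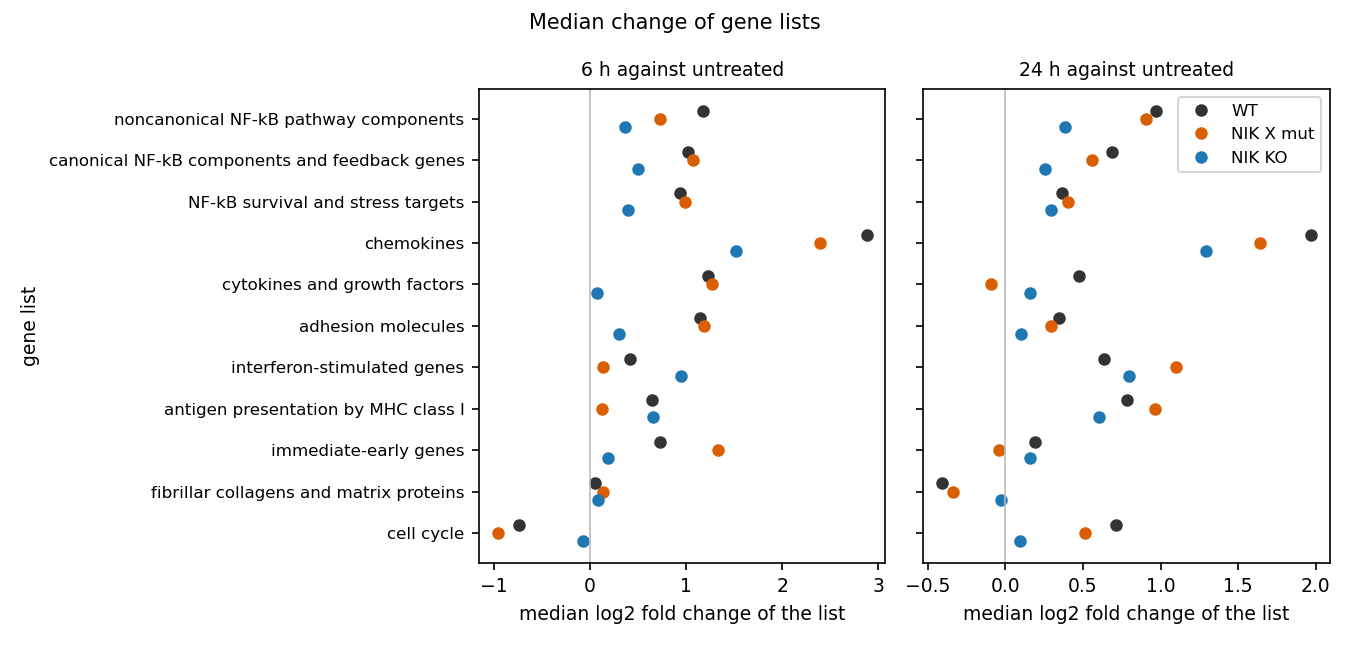
Median log2 fold change of 11 gene lists against untreated cells of the same genotype, at 6 h (left) and 24 h (right). The chemokine median at 6 h is 2.88 in WT, 2.39 in MUT and 1.52 in KO.

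Whether the response itself depended on NIK was tested as the difference between the KO and WT changes. At 24 h the response of 30 genes differed, 18 of them with a lower and 12 with a higher change in KO. Nfkb2 changed less by a log2 difference of -1.87 ± 0.24 (adjusted p = 0.000806), Icam1 by -2.43 ± 0.47, Cxcl16 by -2.24 ± 0.40, Nfkbie by -2.72 ± 0.49, Birc3, a ubiquitin ligase that acts on NIK, by -1.62 ± 0.32, and Ccl5 by -5.16 ± 1.03 (n = 2 and 4 per time). Icam1 rose from 23.4 ± 5.55 to 174.8 ± 59.5 CPM in WT and went from 17.7 ± 7.25 to 25.3 ± 2.57 in KO (SD). Positive differences were found for genes that fell in WT, among them Lmcd1 (3.43 ± 0.63), Osr1 (1.78 ± 0.37), Itga11 (1.08 ± 0.23), Trib2 (2.15 ± 0.30) and Spry1, an inhibitor of growth factor signalling (1.65 ± 0.24). The Relb difference did not pass (-0.94 ± 0.27, adjusted p = 0.219).

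At 6 h the KO and WT responses differed for 11 genes. The lower changes were in Gata3, a transcription factor gene (-2.90 ± 0.48), Nfkbie (-2.57 ± 0.49), Icam1 (-2.36 ± 0.46), Slc20a1 (-2.14 ± 0.42), Rnf19b (-1.71 ± 0.23, adjusted p = 0.00223), Spsb1 (-1.46 ± 0.25), Trim47 (-1.44 ± 0.26) and Nfkb2 (-1.26 ± 0.24, adjusted p = 0.0448), and the higher ones in Osr1 (2.28 ± 0.38), Ephb3 (1.67 ± 0.32) and Zfp503 (1.36 ± 0.20). The noncanonical list had a lower response in KO at 6 h (1 of 13, and 4 over the list alone; adjusted p = 0.0173 with an estimated correlation) and at 24 h (2 of 13, and 6 over the list alone; adjusted p = 0.0128 with an estimated correlation), as did the canonical list (1 of 18, and 5 over the list alone, at 6 h, with adjusted p = 0.0173; 3 of 18, and 5 over the list alone, at 24 h, with adjusted p = 0.0345). Adhesion molecules did so at 6 h (1 of 10, and 2 over the list alone, with adjusted p = 0.0114), but at 24 h their adjusted p was 0.364 with an estimated correlation. Interferon-stimulated genes had a difference with a positive median at 6 h, 0.56, which was lost with an estimated correlation (adjusted p = 0.52 with an estimated correlation). Camera with the culture as a block, chosen after seeing the data, also called lists outside NF-kB. At 24 h these included collagens and matrix proteins (adjusted p = 2.2e-07), fibroblast markers (0.0101) and skeletal muscle and pericyte markers (0.00581), all with a positive difference. Melanocyte and Schwann cell markers did so at 6 h (0.0281).

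With the culture as a block, 29 genes differed between KO and WT responses at 6 h and 160 at 24 h, and with the library sets 14 and 110, which included 7 of the 11 (not Osr1, Ephb3, Icam1 and Spsb1) and all 30. DESeq2 called 20 and 63, and a fit of the KO and WT libraries of each comparison alone called 0 and 9. The 11 genes at 6 h became 0 without the KO 6 h library of replicate 1, 1 without the KO 6 h library of replicate 2 or the untreated KO library of replicate 1, 5 without the untreated WT library of replicate 2 or 4 or the WT 6 h library of replicate 1, 6 without the WT 6 h library of replicate 3 or the untreated KO library of replicate 2, and 7 without the WT 6 h library of replicate 4. The 30 genes at 24 h became 7 without the untreated KO library of replicate 1 or the KO 24 h library of replicate 2, 8 without the KO 24 h library of replicate 1, 16 without the untreated KO library of replicate 2, and 19 without the untreated or the 24 h library of WT replicate 2.

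The MUT and WT responses did not differ for any gene in edgeR at 6 h or at 24 h, and DESeq2 called 0 and 5. In edgeR 267 genes at 6 h and 507 at 24 h had an unadjusted p under 0.05. Both counts lie below the 566.85 expected by chance. The test was thus conservative here, and a count of 0 does not show that the responses were equal. Nfkb2 differed by -0.24 ± 0.24 at 6 h and -0.43 ± 0.24 at 24 h, and Relb by 0.54 ± 0.25 and -0.06 ± 0.26. The lists past camera, 2 at 6 h and 4 at 24 h, were all lost with an estimated correlation, among them noncanonical components at 24 h (median -0.22; adjusted p = 0.944 with an estimated correlation) and interferon-stimulated genes at 24 h (median 0.39; adjusted p = 0.98 with an estimated correlation). A difference of log2 1 was recovered in 10% of simulated genes at 6 h and 12% at 24 h. The culture block called 9 genes at 24 h. With WT reduced to replicates 1 and 2, which lie in the other library set, 28 genes differed at 6 h and 0 at 24 h, and with replicates 3 and 4 the counts were 0 and 7.

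Between MUT and KO, the responses differed for 0 genes in edgeR without a block at both times (578 and 813 with an unadjusted p under 0.05, DESeq2 0 and 5). The fits with a block for the culture did call genes at 24 h, with counts given under the processing. The Nfkb2 difference was 1.02 ± 0.28 at 6 h and 1.44 ± 0.28 at 24 h (adjusted p = 0.596 and 0.207), and that of Relb at 6 h was 1.42 ± 0.30 (adjusted p = 0.455). At 6 h 13 lists passed camera and none with an estimated correlation, where canonical components (median 0.62) gave an adjusted p = 0.0585 with an estimated correlation. With the library sets, Gm6136 (9.60) passed at 6 h, and Ccl2 (2.02), Nab2 (-2.55), Pcbp4 (-2.84) and Slc7a5 (-2.52) passed at 24 h. These were chosen after their values were seen. A fit of the libraries of MUT and KO alone called 66 genes at 6 h and 13 at 24 h.

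The size of the response was also summarised per culture, as the median log2 change in the WT direction. Each WT culture was set beside the MUT and KO cultures on the same genes, those called in the other 3 WT cultures, a comparison added after seeing the data. At 24 h WT cultures 1 to 4 had medians of 1.56, 1.94, 1.74 and 1.54 on 270, 110, 142 and 156 genes. Both MUT and both KO cultures lay below WT on each of these lists, at 58.2% to 70.9% of the WT value for MUT and 17.1% to 19.6% for KO. At 6 h the WT medians were 1.24, 1.57, 2.46 and 1.95 on 177, 93, 37 and 59 genes. KO was lower on each list, at 32.6% to 39.1%, while MUT was above WT cultures 1 and 2 and below cultures 3 and 4, at 81.4% to 111%. The lists share genes, so no p-value is given. On the genes called in all 4 WT cultures, MUT and KO differed with an exact permutation p = 0.333 at each time (two-sided), the smallest that 6 assignments allow.

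On genes chosen in 2 WT cultures and measured in the others, MUT retained 100.4% of the WT response at 6 h and 72.4% at 24 h, and KO 42.4% and 19.2%. Over 4 usable choices of WT cultures the KO values ranged from 37.7% to 46.7% at 6 h and from 17.1% to 20.5% at 24 h, and the MUT values from 64.9% to 79.5% at 24 h. The MUT value at 6 h was less certain, from 90.2% to 195.6%, and was 203% without WT replicate 2. For each mutant, 1 of these 4 choices measured the WT cultures of its own library set, on genes chosen in the other set. By that choice MUT retained 90.2% at 6 h and 68.0% at 24 h, and KO 46.7% and 17.1%. For KO at 6 h it covered 778 genes, which changed by only 0.559 in WT replicates 1 and 2.

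**Figure D4:**
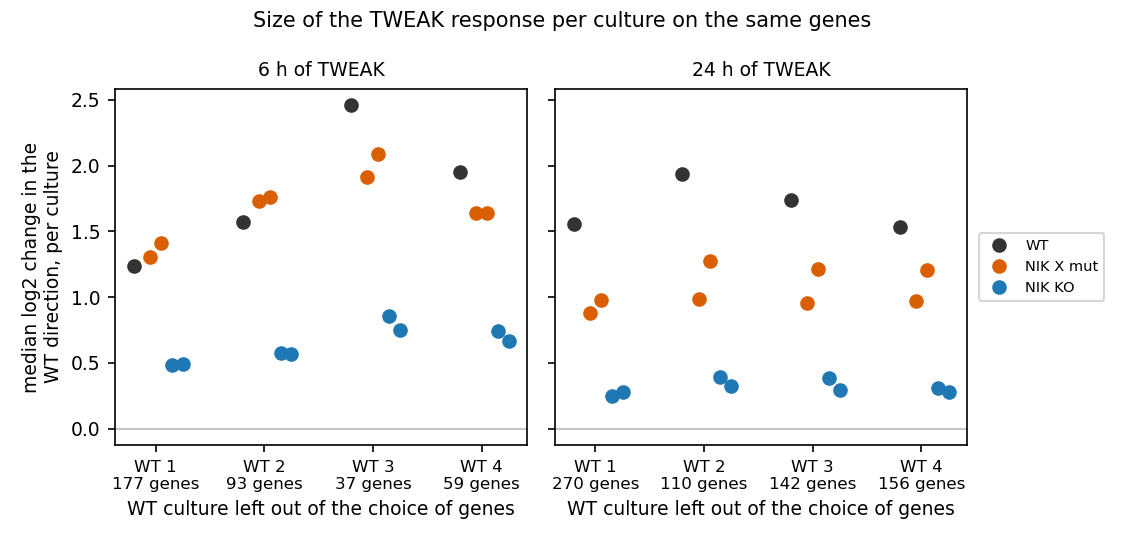
Median log2 change after TWEAK in the WT direction per culture, at 6 h (left) and 24 h (right). Each position shows the WT culture left out of the choice of genes and the 2 MUT and 2 KO cultures on those genes, whose number is given below. At 24 h WT culture 4 (1.54) lies above MUT (0.97 and 1.21) and KO (0.31 and 0.28).

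Gene by gene within a library set, 623 of 1174 genes called in WT replicates 3 and 4 at 6 h were also called in MUT, and 97.7% had the same sign. At 24 h this was 168 of 517 genes, with 94.4% of the same sign. Another 264 genes at 6 h and 170 at 24 h were called in MUT but not in WT replicates 3 and 4. The response retained was measured on genes chosen in WT, so it does not cover changes called only in MUT or only in KO. In KO, 10 of 409 genes called in WT replicates 1 and 2 at 6 h and 2 of 873 at 24 h were also called, with 84.1% and 65.1% of the same sign. In levels at one time, which include differences present before treatment, MUT differed from WT replicates 3 and 4 in 3 genes at 6 h and 229 at 24 h, and KO from WT replicates 1 and 2 in 175 and 528.

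The authors' deposited table calls 391 genes in WT at 6 h, 382 in WT at 24 h, 229 and 81 in MUT, and 9 and 3 in KO, and every gene it calls has an absolute log2 change of at least 1. Its comparisons of genotypes at one time, which include differences present before treatment, call 175 genes between KO and WT at 6 h and 296 at 24 h, and 9 and 98 between MUT and WT. In the authors' deposited table Map3k14 does not pass between untreated KO and WT (-6.30, adjusted p = 0.0845).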

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

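The tests of sex, of litter or preparation and of the library sets were chosen after the results were seen, as were the values with the library sets as groups.

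The first pattern was the position of WT replicates 1 and 2 with KO, and of WT replicates 3 and 4 with MUT, at every time. Sequencing depth did not account for it, since the sets explained a share of 0.940 of principal component 1 within times before and 0.944 after all libraries were thinned to 889863 UMIs. Sex went with the sets except in WT replicate 2, as WT replicate 1 and KO had few or no Y-linked UMIs. WT replicate 2, with 228 Y-linked UMIs and no Xist UMI, lay nearer to them on principal component 1 in 3 of its 3 libraries. On a score along the untreated WT set difference, computed without the WT library scored, it lay at 0.038. WT replicate 1 and KO lay at 0.164 to 0.375, and WT replicates 3 and 4 and MUT at -0.390 to -0.267. A single culture between the sets cannot exclude sex. A shared litter, mouse line or day of preparation cannot be told apart, because the labels give neither the litter nor the extraction kit of a sample. Across genes the untreated difference between WT replicates 1 and 2 and replicates 3 and 4 correlated with that between KO and MUT (r = 0.485), but this restates how the sets were found and decides nothing. What lies behind the sets stays open, sex and a difference between the mouse lines included.

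The second pattern was the smaller response in KO, where the responses of 11 genes at 6 h and 30 genes at 24 h differed from those in WT. Fewer libraries and lower depth did not account for it: WT replicates 1 and 2, thinned to the KO totals in 10 draws, still gave a median of 289 genes at 6 h (282 to 297) and 529 at 24 h (497 to 552), where the same fits called 11 and 3 in KO. The library set did not, since KO retained 17.1% of the response of WT replicates 1 and 2 at 24 h, on genes chosen in WT replicates 3 and 4. Sex did not, as far as 1 culture can show. WT replicate 1 held Xist and no Y-linked UMI. Its median change at 24 h was 1.56 against 0.25 to 0.28 in KO on the same 270 genes. Not every list had a smaller response in KO. With the culture as a block, interferon-stimulated genes had a median of 0.97 in KO and 0.38 in WT at 6 h, and 0.83 and 0.70 at 24 h. MHC class I presentation had 0.65 and 0.66 at 6 h, and 0.60 and 0.80 at 24 h. The interferon difference at 6 h did not pass camera with an estimated correlation. A biological hypothesis is that loss of NIK lowers the TWEAK response of genes chosen in WT. Its limit is that KO and the WT of its set are 2 cultures each, and that litter and preparation within the set were not recorded. WT and KO littermates prepared together, or KO cells given NIK back, would decide the hypothesis, and these data hold neither.

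The third pattern was the smaller response in MUT than in WT at 24 h, 72.4% of the held-out WT response on genes chosen in WT. It was not explained by the library set, since MUT retained 68.0% against WT replicates 3 and 4 on genes chosen in WT replicates 1 and 2. GC content did not explain it either, since 73.3% remained after each library's trend with GC was removed. That step moved values by a mean of 0.0437 (log2). In edgeR without a block, no single gene's response differed between MUT and WT at 24 h, and none did with the library sets as groups. Without a block 507 genes had an unadjusted p under 0.05, below the 566.85 expected by chance, so that test was conservative. DESeq2 called 5. The fit with a block for the culture called 9. Crossing the KO numbers as well gave 25, but that pairing was picked from these same data and the MUT libraries were not paired anew. The 25 is therefore no further support. With WT reduced to replicates 3 and 4, the responses of 7 genes differed. In levels, MUT differed from WT replicates 3 and 4 in 1 gene untreated, 3 at 6 h and 229 at 24 h. In the authors' deposited table Nfkb2 is lower in MUT than in WT at 24 h (-0.87, adjusted p = 0.000163). It is also lower there at 6 h (-0.67, adjusted p = 0.0470), so this gap is not particular to 24 h. Before treatment the difference in that table is -0.46 (adjusted p = 0.778). In edgeR the Nfkb2 response at 24 h differed by -0.43, which did not pass the test. A weaker late response in MUT is therefore a hypothesis that rests on 2 cultures, and more MUT cultures with WT littermates would decide it.

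For the responses in WT, 2 of 35 splits of the libraries, the real one included, gave at least as many genes as the real one at 6 h. The count was again 2 at 24 h, so chance is not excluded by that count alone. The real splits gave 224 genes at 6 h and 428 at 24 h in the WT libraries alone, and the highest other splits 563 and 868. The latter follow the library sets and point to a structure of the samples, and each of the remaining splits gave 0 genes at 6 h and at most 2 at 24 h. With the sets as groups, WT gave 1271 and 1760 genes, but the sets were read from these same libraries, so those counts do not bear on chance. On genes chosen in the other 3 WT cultures, each WT culture changed in the same direction, by medians of 1.24 to 2.46 at 6 h and 1.54 to 1.94 at 24 h. The splits along the library sets were set aside only after their counts were seen, so the remaining splits do not decide about chance. The held-out medians argue against chance for the genes chosen in that way. No held-out medians of other splits were set beside them, so they carry no p-value.

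Among 35 values tested for a library far from the others of its group, 4 stood out, where chance gives about 1 in 20. Ribosomal protein genes took 10.2% of the UMIs of untreated WT replicate 3, against 8.96% to 9.02% in the others. Nfkb2 was at 123 CPM in untreated WT replicate 1, against 94.3 to 95.2. Relb was at 99.6 CPM in WT replicate 2 at 24 h, against 80.4 to 83.2. Tnfrsf12a was at 793 CPM in WT replicate 1 at 24 h, against 374 to 425.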

How the results depend on the processing

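The library sets, the crossed KO block, the block in the list tests, and the leave-outs and same-gene lists of response retained were chosen after seeing the data. DESeq2's size factors within edgeR kept all 15 gene counts within 1.5 times, and no named gene past the test in the main fit changed sign under any alternative. Named genes not past it did, such as Tnfrsf12a in the MUT and KO difference at 6 h (1.23, and -0.39 at the lowest). No list passed in opposite directions. Over the named genes, 5250 planned values kept their side of the threshold, 967 were weaker and 30 stronger, and of the added ones 668, 5 and 11. Where a count moved, the cause was not tested, except that leave-outs and reduced WT have fewer samples. Changes of log2 1 were recovered in 16% to 29% of simulated genes for the responses in MUT and KO, and in 8% to 12% for their differences from the WT response.

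DESeq2 called 120 genes in MUT and 3 in KO at 24 h, and differing responses of 20 genes between KO and WT at 6 h and 63 at 24 h, 5 between MUT and WT at 24 h and 5 between MUT and KO at 24 h. Before treatment it called 2 for MUT and WT, 0 for KO and WT and 12 for MUT and KO. Without the filter, KO at 24 h gave 1 gene. With an absolute log2 change of at least 1, WT gave 411 genes at 6 h and 417 at 24 h. With WT reduced to 2 numbers the medians were 274.5 for WT at 6 h (175 to 1495), 321.5 for WT at 24 h (166 to 916) and 4 for KO against WT at 6 h (2 to 256), with the 3 highest values from WT 3 and 4, which share a library set. KO against WT at 24 h ranged from 7 to 125. MUT against WT gave 28 at 6 h with WT 1 and 2 and 7 at 24 h with WT 3 and 4, and 0 with every other choice.

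In fits of only the groups compared, WT gave 224 and 428 genes at 6 and 24 h, MUT 1345 and 1104, and KO 15 and 4. The responses of KO and WT differed for 0 and 9 genes and those of MUT and KO for 66 and 13, and untreated MUT and KO differed for 560.

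With the culture as a replicate block, WT gave 1314 and 1770 genes at 6 and 24 h, MUT 853 and 355, and KO 14 and 4. Responses differed for 29 (6 h) and 160 (24 h) genes between KO and WT, for 9 between MUT and WT at 24 h and for 7 between MUT and KO at 24 h. With that block and the KO numbers crossed, the counts were 1434 and 1940 in WT, 942 and 481 in MUT, and 16 and 4 in KO, with differing responses of 32 and 222 genes between KO and WT, 1 and 25 between MUT and WT, and 4 and 87 between MUT and KO. The crossed pairing was picked because KO libraries of equal number correlated negatively in these same data, which can lower the residual spread. Its higher counts are no independent check. With limma-voom and a random block, WT at 24 h gave 1430, MUT 536 and 209, and KO at 24 h 2, with differing responses at 24 h of 71 genes between KO and WT, 4 between MUT and WT and 3 between MUT and KO. It called 0 untreated differences of KO from WT and 0 of MUT from KO.

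With the library sets as groups, WT gave 1271 and 1760 genes, MUT 887 and 338, and KO 3 at 24 h. The responses of 110 genes differed between KO and WT at 24 h, and of 1 and 4 between MUT and KO. Untreated cells differed in 1 gene (MUT and WT), 3 (KO and WT) and 3 (MUT and KO).

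Of the lists called with the preset correlation, those left with an estimated one were 6 in WT at 6 h (from 11), 5 in WT at 24 h (from 13), 7 in MUT at 6 h (from 13), 4 in MUT at 24 h (from 10), 3 for KO against WT at 6 h (from 10) and 2 at 24 h (from 8). For the differences of MUT from WT and from KO, at both times, and all 3 untreated comparisons 0 were left. With fry, 7 passed in MUT at 6 h, 4 in KO at 6 h (from 9), 0 in KO at 24 h (from 6), 3 and 2 for KO against WT, and 0 in the same differences of MUT and the untreated comparisons. With the culture as a block, 20 list tests over the 12 responses and response differences passed that had not passed before and 2 no longer did, and camera called 5 lists for MUT against WT at 6 h (from 2) and 7 for MUT against KO at 24 h (from 2).

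Leaving out 1 library or 1 number gave from 353 to 938 genes in WT at 6 h, 489 to 736 in WT at 24 h, 13 to 63 in MUT at 6 h, 8 to 23 in MUT at 24 h, 1 to 3 in KO at 6 h and 0 to 1 in KO at 24 h. Without KO replicate 2, the 3 genes called in KO at 6 h all fell and none was among the 9. Differing responses ranged from 0 to 15 genes between KO and WT at 6 h and 0 to 52 at 24 h, were 0 between MUT and WT at 6 h and 0 to 2 at 24 h, and ranged from 0 to 2 between MUT and KO at 6 h and 0 to 6 at 24 h. Untreated differences ranged from 0 to 1 (MUT and WT), 1 to 2 (KO and WT) and 0 to 1 (MUT and KO). A group left with 1 library was assumed to vary like the others. The response retained ranged from 91.8% to 203% in MUT at 6 h, 36.6% to 48.5% in KO at 6 h, 68.1% to 75.2% in MUT at 24 h and 17.9% to 19.95% in KO at 24 h, and was 244% in MUT at 6 h over falling genes alone, which left 1 usable choice of WT cultures.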

Other observations

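The values with the library sets as groups were chosen after the results were seen. Cell cycle genes, which include Mki67 and Top2a, differed with the library sets in untreated level and in response at 6 h. At 24 h the response did not follow the sets, as WT replicates 1 and 2 lay above the other set and KO below it. Over 47 genes the median log2 CPM of untreated cultures was 4.50 and 4.06 in WT replicates 1 and 2, 4.40 and 4.20 in KO, 5.92 and 6.01 in WT replicates 3 and 4, and 6.00 and 5.89 in MUT. At 6 h the median change was -1.10 and -0.94 in WT replicates 3 and 4 and -0.86 and -0.93 in MUT, against -0.09 and 0.01 in WT replicates 1 and 2 and -0.05 and -0.08 in KO. At 24 h it was 0.88 and 0.92 in WT replicates 1 and 2, 0.50 and 0.60 in WT replicates 3 and 4, 0.51 and 0.45 in MUT, and 0.09 and 0.06 in KO.

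Compared with the WT cultures of its own set, KO had a lower cell cycle response at 24 h, with a median difference of -0.87 and 19 of 47 genes lower when adjusted over the list alone (adjusted p = 0.00277 with an estimated correlation). In the comparison with all WT cultures the median was -0.57 and the adjusted p was 0.836 with an estimated correlation. At 6 h the median difference from WT of the same set was -0.05. For MUT the same comparison gave medians of 0.05 at 6 h and 0.06 at 24 h.

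Iigp1, an interferon-inducible GTPase, changed by 4.33 ± 0.92 in KO at 24 h (adjusted p = 0.296; 43 UMIs against 2 in untreated KO libraries, a ratio of 21.8 with a 95% exact interval of 5.69 to 186 for counting error only) and by 0.34 ± 0.43 in WT, and the KO and WT responses did not differ past the test (3.99 ± 1.05, adjusted p = 0.164). It was chosen after its values were seen. In the authors' deposited table the 1 gene that passes between untreated MUT and WT is Ubb-ps, a pseudogene, with a fitted log2 change of -19.3, a fit against MUT libraries that hold no UMI of it. The assignment of reads to a pseudogene is uncertain, and no fold of it was computed from the counts.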
